A study of Mus musculus with 3 samples.

How the data were processed

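Polyadenylated RNA was sequenced from regulatory T cells (Tregs) of the mouse that had been through inflammation, collected at 12 weeks of age. The labels name 1 biosample from 1 donor and 3 libraries, called technical replicates 1 to 3 of biological replicate 1, so all 3 libraries form 1 group. The inflammatory treatment, the sorting gate and the sex of the donor were not given in the sources used here.

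Each library came with deposited gene and transcript tables quantified against GENCODE annotation M21 on mouse assembly mm10, and with a further gene table counted against annotation M4. The authors' gene tables hold expected counts, which are read numbers shared out among genes by a model and need not be whole, and posterior mean counts with their standard deviation, per the file headers. TPM values (transcript abundance scaled to 1 fixed sum over genes, transfer RNA rows and spike-in rows), posterior mean TPM with lower and upper bounds, and FPKM values were also computed by the authors, per the file headers. The level of those bounds is not stated. The deposited transcript tables add the percent of a gene's TPM that each transcript takes, per the file headers. The deposited M4 tables hold whole-number counts per gene. The aligner, the counting program and the handling of duplicate reads were not given in the sources used here. The effective length in the M21 tables is 49 bases below the length of every gene and transcript with reads. TPM values share 1 total, so an abundant transcript in a library lowers the TPM of every other gene in it.

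All 55536 gene identifiers of the M21 tables were found in the M21 annotation, which gave symbols, biotypes and mm10 coordinates. Of the 22457 genes in the M4 tables, 22195 matched an M21 gene by identifier without version. Where a symbol stood on several identifiers, the one with the highest mean count was used. Rows for transfer RNAs, the ERCC spike-ins and the phiX control stayed out of library sizes and tests. They took 0.170% of expected counts in libraries 1 and 2 and 0.218% in library 3. Total expected counts were 35652707, 31665170 and 37810591 in libraries 1 to 3, and M4 totals were 9718021, 8945992 and 9904722.

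The plan for tests, gene lists, gene pairs and named genes was fixed before the data were examined. A gene was called detected at a TPM of at least 1 in all 3 libraries. Expected counts were rounded to whole numbers and scaled by the trimmed mean of M values (TMM) of edgeR 4.0.16 in R 4.3.3. For each gene with a mean count of at least 10, a chi-square test asked whether the 3 libraries differed by more than Poisson counting noise, with Benjamini-Hochberg adjustment at 0.05. This test compares these libraries and no conditions. The common biological coefficient of variation was the square root of the common dispersion of edgeR on an intercept-only design. With 1 group, no quasi-likelihood contrast was run. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

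For each of 26 gene lists, the median over members of the mean log2(TPM + 1) was placed among 10000 random lists of the same size drawn from 22028 protein-coding genes. A fold between 2 genes is the ratio of their mean TPM. An alternative drew them from genes of any biotype with a mean TPM of at least 1. The percentile describes these libraries and is no p-value, since genes are not replicates. For 20 gene pairs, the difference in log2(TPM + 1) was tested by a two-sided exact sign-flip permutation test, whose smallest possible p over 3 libraries is 0.25. A pair was called apart where the difference had 1 sign in all 3 libraries, the ranges over libraries did not overlap, and the authors' TPM bounds did not overlap in any library. In the M4 counts the condition on bounds was left out, so apart is a looser call there. Errors are standard deviations over the 3 libraries, which measure the spread between libraries labelled technical and say nothing about variation between mice. The interval of a share of counts is a 95% Wilson interval and, like the limit that a count of 0 allows, covers counting error only.

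Genes named in the text are all members of the Treg identity, activated and resting lists and of the pairs. They also include the 4 highest and 2 lowest members of other lists by mean TPM (the 4 highest for other cell types) and the 15 genes of highest TPM outside mitochondrial, ribosomal protein, transfer RNA and spike-in rows. The 10 genes with the largest ratio between libraries at a mean count of at least 50, leading transcripts, and sex-linked genes complete the rule. Any other gene is said to have been chosen after its values were seen. Some genes that the rule covers are not reported here. After the data had been seen, list medians of log2 CPM were compared between libraries and placed among 10000 random lists drawn for each member from the 200 genes nearest in mean expression. Lists of 15 secretory genes seen to be high in library 3, of 15 other salivary gland genes and of 10 exocrine pancreas genes were also written then.

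The scripts were tested on simulated data. With Poisson counts of 18253 genes drawn from the real means and library sizes, the chi-square test recovered 98 of 100 genes changed 1.5-fold in 1 library and 100 of 100 changed 2-fold, with 10 false calls. The changed genes all had a mean count of at least 100, so recovery at lower counts was not tested. A simulated coefficient of variation of 0.2 was estimated as 0.19988. Of 100 unchanged lists of 20 genes, 6 fell outside the central 95% of random lists, and all 100 lists shifted by 0.4 on the log2 scale fell above it. The log ratios in that simulation were drawn independently and with the same spread for every gene. Lists of genes with few counts, whose ratios spread more, and lists of genes that move together were therefore not covered. Alternatives covered DESeq2 1.42.0 size factors and dispersions, total-count scaling, other filters, pseudocounts and thresholds, posterior means, FPKM, the M4 counts and leaving out each library.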

Results

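The data describe the transcriptome of Tregs, the CD4 T cells that restrain immune responses under the transcription factor Foxp3, after exposure to inflammation, in mouse material of 12 weeks of age. There were 3 libraries of 1 biosample, with 35652707, 31665170 and 37810591 expected counts. With 1 group, the design implies comparisons between genes and gene groups within the libraries, and between the libraries themselves. Transcripts of 12883 genes reached a TPM of at least 1 in all 3 libraries, 10494 of them protein-coding, and 1822 reached a TPM of at least 100. Across these 12883 genes, log2 values of libraries 1 and 2 had a Pearson r of 0.983, libraries 1 and 3 of 0.984, and libraries 2 and 3 of 0.982. These are correlations across genes, which are not independent replicates.

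The transcripts that mark Tregs were abundant in all 3 libraries. All 19 members of the Treg identity list were detected, with a median of 209 TPM, and the list's median lay above all 10000 random lists. Foxp3 (identifier ENSMUSG00000039521.13, chromosome X, 7573644 to 7595245, plus strand, mm10), the factor that defines the lineage, stood at 97.6 ± 1.04 TPM (SD, n = 3 for this and all later values). Il2ra, a chain of the interleukin-2 receptor, stood at 248 ± 10.7 TPM and its partner Il2rb at 919.7 ± 15.6 TPM. The costimulatory receptors Tnfrsf4 and Tnfrsf18 reached 931 ± 77.8 and 847 ± 85.8 TPM, and the folate receptor family member Izumo1r reached 882 ± 36.2 TPM. Ctla4, an inhibitory receptor of Tregs, stood at 281 ± 46.9 TPM, Ikzf2, which encodes Helios, at 377 ± 50.7 TPM, and Nrp1 at 309 ± 21.4 TPM. The lowest member was Plagl1 at 4.56 ± 2.02 TPM. Nt5e, which turns AMP into adenosine, exceeded Entpd1, which makes AMP from ATP, with 209 ± 13.8 against 56.5 ± 2.39 TPM. Entpd1 minus Nt5e was -1.86 on the log2 scale and -0.57 in the M4 counts per kilobase. Ikzf2 stood 4.44-fold above its relative Ikzf4 in TPM, but in the M4 counts per kilobase, which level off at high expression, this difference was -0.0044 on the log2 scale.

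Genes of the activated and effector Treg list and of the resting and naive T cell list were present together. Whether the same cells expressed both cannot be told from these libraries. All 24 members of the activated and effector list were detected, with a median of 55.7 TPM, and all 16 members of the resting and naive list, with a median of 187 TPM. Both list medians lay above all 10000 random lists. Among activated genes, the costimulatory receptor Icos stood at 279 ± 91.1 TPM, Tnfrsf9 at 299 ± 36.8 TPM, the transcription factor Batf at 251 ± 56.7 TPM, the chemokine receptor Ccr8 at 135 ± 22.4 TPM and Klrg1 at 139.8 ± 41.5 TPM. The lowest were Lag3 at 6.54 ± 2.37 TPM and Havcr2 at 3.53 ± 0.990 TPM. Among resting genes, the transcription factor Tcf7 stood at 451 ± 56.6 TPM, Klf2 at 327 ± 72.1 TPM, Ccr7 at 264 ± 40.0 TPM and the transcription factor Foxp1 at 240.2 ± 21.4 TPM.

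**Figure D1:**
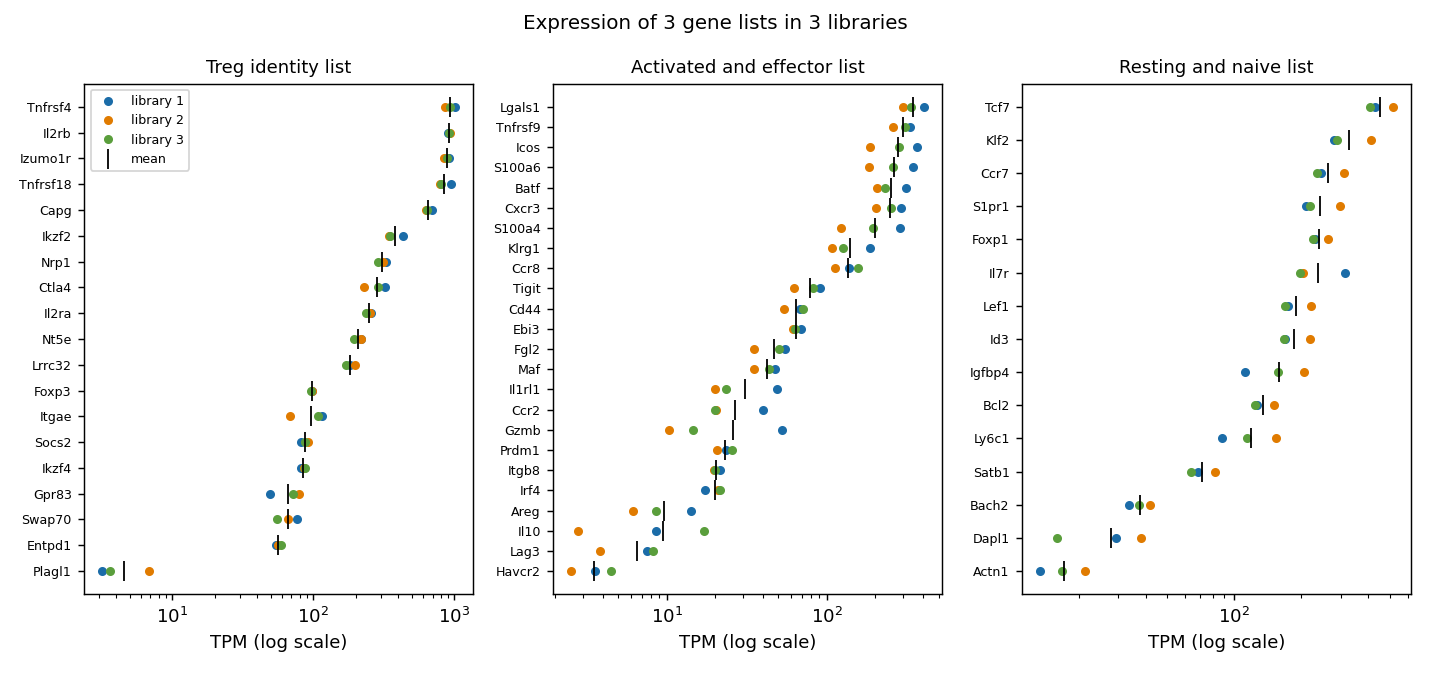
TPM on a log scale of members of the Treg identity, activated and resting lists, with 1 point per library and a tick at the mean. Foxp3 lies at 98.1, 98.4 and 96.5 TPM in libraries 1 to 3, while Gzmb in the activated list lies at 52.6, 10.3 and 14.7 TPM.

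Of the 20 gene pairs, 16 were apart. Bach2, a repressor of effector genes, exceeded Prdm1, which encodes Blimp-1, with 37.7 ± 4.02 against 23.3 ± 2.60 TPM. Without correction for transcript length this order turned around, with Prdm1 higher by 0.22 on the log2 scale. Not apart were Id2 and Id3, at 185 ± 43.4 and 185 ± 29.7 TPM, Il2ra and Il7r, Cxcr3 and Ccr7, and Tnfrsf18 and Tnfrsf4. In the M4 counts per kilobase, which level off at high expression, the last 3 were apart in the other direction, with log2 differences of -0.80, 0.17 and 0.16, and without library 2 Cxcr3 minus Ccr7 was 0.16. Tcf7 stood 2.40-fold above Lef1 in TPM, but by 0.11 on the log2 scale and not apart in those M4 counts. The survival factor Mcl1 stood above Bcl2 by a log2 difference of 1.72 ± 0.08, and the integrin chain Itgb1 lay below Itgb7, with a log2 difference of -1.52 ± 0.13. The chemokine receptor Ccr4, at 31.8 ± 1.57 TPM, lay below Ccr8, with a log2 difference of -2.05. Without correction for transcript length, these 3 differences were 0.94, -0.41 and -1.22. The two-sided exact sign-flip permutation test gave p = 0.25 for each of these 16 pairs, the smallest p that 3 libraries allow, so no pair could pass 0.05.

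Among regulators of helper T cell lineages, Gata3, the regulator of type 2 helper cells, stood above Tbx21, the regulator of type 1 helper cells. Gata3 reached 134 ± 9.74 TPM and Tbx21 25.9 ± 0.780 TPM, a log2 difference of 2.33 ± 0.06 that was 1.18 in the M4 counts per kilobase. The list of lineage factors lay at percentile 98.8 of random lists, with Stat3 at 203 ± 8.56 TPM, Stat6 at 192 ± 17.6 TPM and Stat4 at 152 ± 17.2 TPM. Against random lists of genes with a mean TPM of at least 1, that percentile was 88.9.

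Effector cytokines were low. Of 13 in the list, 4 were detected, and the list lay at percentile 28.6. It lay below all random lists of genes with a mean TPM of at least 1. With a list median of 0.353 TPM, under that minimum, this was set in advance. Tnfsf11, which encodes RANKL, stood at 59.7 ± 7.64 TPM, Tnf at 39.1 ± 5.51 TPM and Ifng at 10.6 ± 4.06 TPM. Il22 and Il3 had 0 counts in each library, which allows up to 3 counts. Of 12 suppressive mediators, 11 were detected, at percentile 98.1, or 80.5 against genes with a mean TPM of at least 1. Tgfb1 stood at 117 ± 3.59 TPM, above Il10 by a log2 difference of 3.77 ± 1.14 (3.08 in the M4 counts per kilobase). Il10 had 8.59, 2.78 and 17.1 TPM in libraries 1 to 3. Ebi3, a chain of interleukin-35 and interleukin-27, stood at 64.6 ± 3.74 TPM, while Il12a, the other chain of interleukin-35, had 17 counts in library 1 and 0 in the others. The 10 inhibitory receptors lay at percentile 99.9, led by Ctla4, Pdcd1 at 215 ± 37.1 TPM and Vsir at 191 ± 13.3 TPM, with Cd244a lowest at 0.613 ± 0.169 TPM. The 24 chemokine and homing receptors lay above all random lists, with Selplg at 746 ± 52.8 TPM and Itgal at 282 ± 2.61 TPM, and with Ccr1 and Cx3cr1 lowest at 0.623 ± 0.373 and 0.103 ± 0.0289 TPM.

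Genes of antigen receptor signalling and of metabolism were high. All 16 members of the T cell receptor complex and proximal signalling list exceeded a mean of 100 TPM, with a median of 671 TPM. They included the receptor constant regions Trbc2 at 3399 ± 97.1 TPM and Trac at 2884 ± 174 TPM, and the kinase Lck at 1249 ± 50.2 TPM. The TNF receptor and NF-kB list, with Nfkbia at 629 ± 31.7 TPM and Traf1 at 370.2 ± 22.2 TPM, the oxidative phosphorylation list, with Atp5b at 880.1 ± 28.5 TPM, and the glycolysis list, with Ldha at 820.2 ± 29.9 TPM, also lay above all random lists, as did the housekeeping list. Among enzymes that start glycolysis, Hk1 stood at 98.4 ± 4.62 TPM and Hk2 at 1.43 ± 0.624 TPM, a difference of 5.39 ± 0.38 in log2(TPM + 1), or 6.09 with 0.1 added in place of 1. The glucose transporter Slc2a3 stood 1.54-fold above Slc2a1 in TPM, but in the M4 counts per kilobase, which level off at high expression, the log2 difference turned around, to -0.21, and without length correction it was 1.22. The interferon response list lay at percentile 99.97, with Ly6a at 571 ± 209 TPM and Irf1 at 345 ± 11.9 TPM. The immediate early and stress list lay at percentile 99.99, with Jund at 670.4 ± 33.3 TPM, Junb at 518 ± 61.9 TPM and Fosb at 1.97 ± 0.704 TPM. The proliferation list, at percentile 80.6, or 4.2 against genes with a mean TPM of at least 1, had its replication genes Pcna at 115 ± 10.4 TPM and Mcm2 at 43.9 ± 3.82 TPM, and its mitotic genes Tpx2 and Bub1 at 1.58 ± 0.332 and 0.897 ± 0.722 TPM.

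Markers of other cell types were mostly low, with exceptions. Ighm, the immunoglobulin mu heavy chain, stood at 1395 ± 187 TPM, while the other B cell genes Cd79b, Cd79a and Ighd stood at 30.4 ± 1.49, 16.7 ± 1.68 and 15.2 ± 2.48 TPM. Cd74, the invariant chain of antigen presentation, stood at 386 ± 21.9 TPM and H2-Ab1 at 31.6 ± 8.23 TPM. Percentiles among random lists were 71.6 for B cells, 51.2 for plasma cells, 58.5 for CD8 T cells, 10.6 for NK cells, 26.0 for gamma delta T cells, 19.3 for myeloid cells, 20.3 for dendritic cells, 48.6 for erythroid cells and platelets, and 42.6 for stromal and epithelial cells. Against genes with a mean TPM of at least 1, they were 3.63 for B cells, 0.01 for plasma cells and 19.5 for CD8 T cells. The 6 other lists lay below all those random lists. Their medians of 0.135 to 0.95 TPM are under that minimum, so this place was largely set in advance. Without library 1, the NK cell percentile among protein-coding genes was 4.43. None of the 12 myeloid genes was detected in all 3 libraries, and 1 of 8 NK genes was. The plasma cell gene Igkc stood at 87.7 ± 22.9 TPM, Hbb-bs of red cells at 11.5 ± 5.51 TPM, the endothelial and leukocyte gene Pecam1 at 74.0 ± 8.08 TPM and the epithelial gene Epcam at 32.1 ± 5.83 TPM. Cd4 exceeded Cd8a by 7.22 ± 0.63 in log2(TPM + 1), by 7.94 with 0.1 added in place of 1 and by 5.76 in the M4 counts per kilobase, and Cd8b1 stood at 19.2 ± 3.73 TPM. The sex-linked list lay at percentile 92.3. Its Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty stood at 82.1 ± 2.93, 70.1 ± 5.98, 34.6 ± 4.79 and 30.6 ± 4.78 TPM, and Xist, the RNA that silences an X chromosome in females, had 0, 0 and 12 counts in libraries 1 to 3.

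Among the genes of highest TPM were Tmsb4x at 13828 ± 1062 TPM, the class I antigen presentation genes H2-K1, B2m and H2-D1 at 11203 ± 595, 7179.9 ± 732 and 5289 ± 326 TPM, Malat1 at 4105 ± 762 TPM, and the actin regulator Pfn1 at 3877 ± 192 TPM. H2-K1 and H2-D1 are close relatives whose reads the quantification could share. The 15 highest also held Bpifa2, which came almost wholly from library 3, as described with the library comparison.

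The authors' transcript estimates gave Foxp3 as 51.2 ± 5.69% Foxp3-207, annotated as a target of nonsense-mediated decay, and 27.5 ± 1.26% Foxp3-206, annotated as protein-coding. For Ikzf2, the retained-intron transcript Ikzf2-205 took 72.6 ± 1.21% and the protein-coding Ikzf2-201 took 14.6 ± 0.958%. Ctla4 came almost wholly from Ctla4-201, with 98.7 ± 0.876%. Ptprc, which encodes CD45, was led by Ptprc-203 with 36.5 ± 0.738% and Ptprc-204 with 24.3 ± 0.471%. Il1rl1, the receptor for interleukin-33, was led by Il1rl1-201 with 60.9 ± 8.67%, followed by Il1rl1-202 with 18.2 ± 7.60%. These shares are model estimates from reads that several transcripts of a gene have in common.

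The 3 libraries differed by more than Poisson counting noise of reads. Mostly secretory genes made the widest gaps, and they were high in library 3 only. Bpifa2, a secreted protein of saliva, had 45, 136 and 891348 counts in libraries 1 to 3, which is 39890.2 TPM in library 3. Smr3a had 10, 7 and 127418 counts, Amy1, the salivary amylase, 40, 66 and 118645, Chia1 5, 4 and 83257, Car6 3, 3 and 32805, and Pip 3, 2 and 19961. The gene 2310057J18Rik had 0 counts in libraries 1 and 2 and 24998 in library 3, and BC037156, Crisp1 and Cst10 complete the 10 largest ratios, all highest in library 3. The list of 15 secretory genes, written after their values were seen, held 3.53% of the gene counts of library 3 (95% Wilson interval 3.52 to 3.54%), 0.000816% of library 1 (0.000726 to 0.000914%) and 0.00103% of library 2 (0.000925 to 0.00115%).

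**Figure D2:**
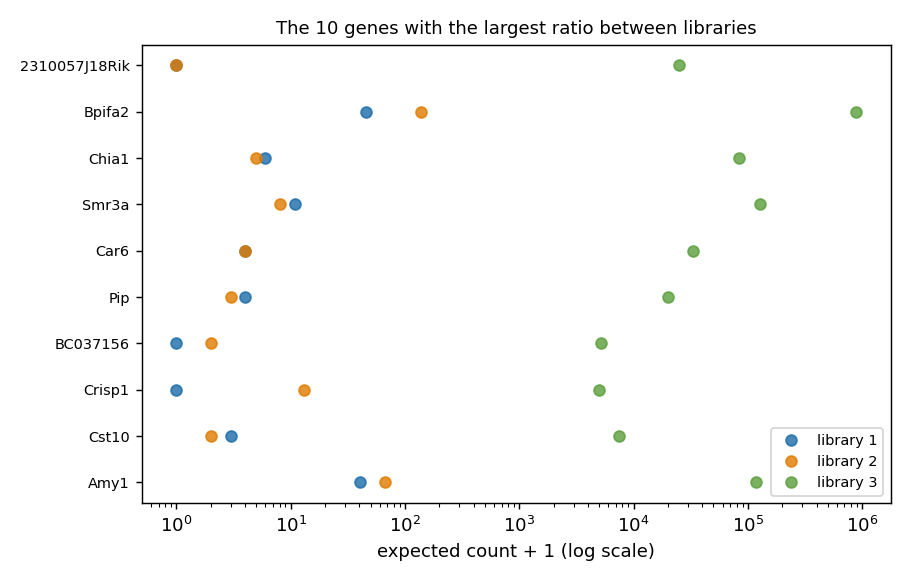
Expected count plus 1, on a log scale, of the 10 genes with the largest ratio between libraries, with 1 point per library. All 10 lie highest in library 3, led in counts by Bpifa2 with 891348.

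The chi-square test against Poisson noise, with Benjamini-Hochberg adjustment, called 14052 of 18253 genes (77.0%) different between libraries. The test counts reads as independent molecules, which amplified reads are not, so it covers counting error of reads only. A ratio of at least 2 between the highest and lowest library was met by 4925 of them. Such ratios were found for 61.4% of genes with mean counts from 10 to 100, 12.7% from 100 to 1000 and 0.475% from 1000 upward. Each pair of libraries differed, with 11027 genes called between libraries 1 and 2, 9200 between 1 and 3, and 10270 between 2 and 3, so none was 1 library deposited again. The common biological coefficient of variation from edgeR was 0.396. It was 0.233 for genes with a mean count of at least 50 and 0.208 in the M4 counts, where 6238 of 12020 genes (51.9%) were called different. Without library 2 and with the scaling refitted, 9218 genes were called. Nothing in the labels says that the libraries came from separate mice, so these values measure the spread between libraries labelled technical.

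Gene groups also moved between libraries, in comparisons added after the data had been seen. Library 2 had lower levels of activated genes and higher levels of resting genes than both others. Of the 24 activated genes, 23 were higher in library 1 than in library 2, with a median log2 ratio of 0.57, and 0 were higher in library 2 than in library 3, with a median of -0.46. Of the 16 resting genes, 15 were lower in library 1 than in library 2, with a median of -0.38, and 15 were higher in library 2 than in library 3, with a median of 0.28. Gzmb, which encodes a cytotoxic granule protease, had 52.6, 10.3 and 14.7 TPM in libraries 1 to 3, Icos 369, 186 and 281, Klf2 281, 409.8 and 289, and Igfbp4 112, 206 and 157. Il7r ran against its list, with 314, 203 and 197 TPM. Interferon response genes were higher in library 1, with median log2 ratios of 0.43 over library 2 and 0.76 over library 3, where 16 of 17 were higher. Mx1 had 14.0, 2.54 and 3.42 TPM. Of 11 suppressive mediators tested, 7 were higher in library 1 than in library 2, with a median of 0.50, and 8 were lower in library 2 than in library 3, with a median of -0.44. Of the list's 12 members, 6 also stand in the activated list; the 5 others tested had medians of -0.10 and 0.05, inside the random range. Immediate early and stress genes were higher in library 3, with medians of -0.26 for library 1 over 3 and -0.39 for library 2 over 3, and Hspa1b, a heat shock protein, had 164, 190.4 and 314 TPM. Library 3 was also the one with the secretory transcripts (3.53% of gene counts), and mitochondrial genes took 1.32% (95% Wilson interval 1.32 to 1.33%), 1.42% (1.41 to 1.42%) and 1.68% (1.67 to 1.68%) of gene counts in libraries 1 to 3. Myeloid genes had medians of -1.68 for library 1 over 3 (1 of 6 higher, percentile 0.36) and -3.37 for library 2 over 3 (0 of 6 higher, percentile 0.23). The epithelial keratins Krt8 and Krt18, chosen after their values were seen, had 5, 5.80 and 90.1 and 80, 9 and 172 counts. The keratins Krt7 and Krt19, members of the list of other salivary gland genes and named here after their values were seen, were lowest in library 3. Their TMM-scaled counts were 6.74, 5.59 and 3.87 and 11.5, 7.70 and 4.76. The stromal and epithelial list stayed inside the random range. Proliferation genes had a median of 0.50 for library 1 over 3. Of 75 medians computed over 25 lists, 11 lay outside the range of 10000 random lists matched on expression, all of them named above; those of the myeloid list lay inside it. The Treg identity list, with medians of -0.01, -0.02 and -0.04, stayed inside that range, as did the T cell receptor and housekeeping lists. In the M4 counts, the median for library 1 over 2 was 0.31 for activated genes (random lists -0.16 to 0.21) and -0.16 for resting genes, inside the random range of -0.17 to 0.21. That of interferon genes for library 1 over 3 was 0.40 there (random lists -0.18 to 0.18).

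**Figure D3:**
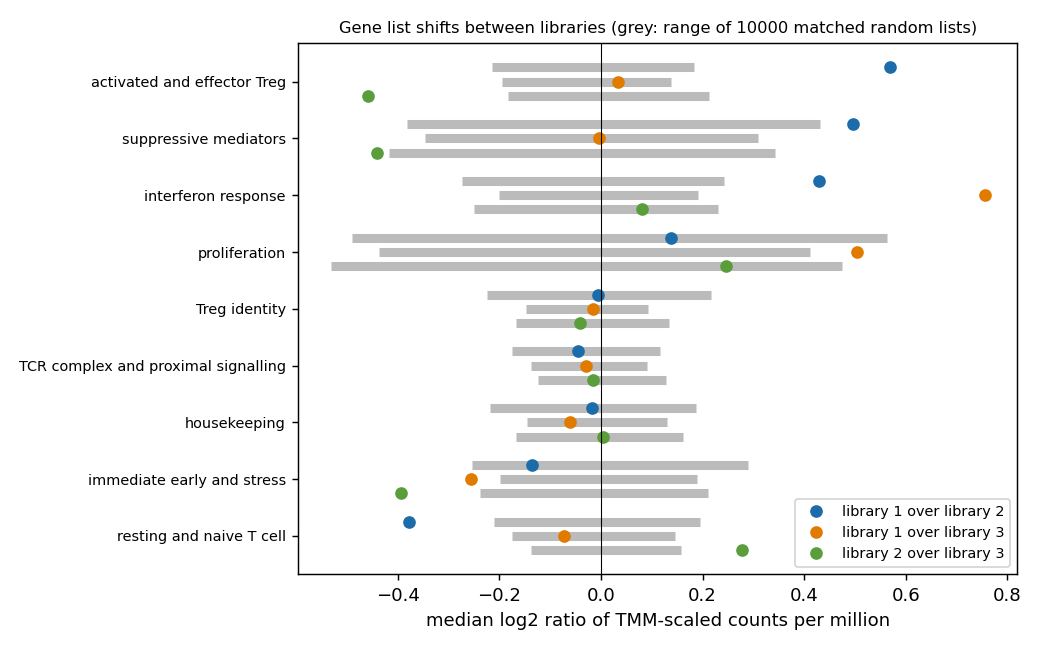
Median log2 ratio of TMM-scaled CPM for 9 gene lists and 3 library pairs (points), with the full range of 10000 matched random lists as grey bars. Activated genes lie at 0.57 and -0.46 for library 1 over 2 and library 2 over 3, outside the bars, and the Treg identity list lies inside them.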

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

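Reads were also counted outside the genes, in rows that entered no comparison. The phiX control, a bacteriophage genome often added to sequencing runs, had 56975, 51191 and 78884 counts in libraries 1 to 3. Transfer RNA rows had 3526, 2557 and 3466 counts. Both stand out because they lie above 3 counts, the upper limit that a count of 0 allows, and the ERCC spike-in rows had 0 counts in each library.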

How the results depend on the processing

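Chosen after seeing the data were the M4 counts and the filter on posterior standard deviation for the genes differing, the M4 counts, the filter at 50 and the removal of salivary genes for the coefficient of variation, and all list ratios between libraries. No paired analysis was possible because the libraries form 1 group. The count of 14052 genes differing between libraries became 4925 when a ratio of at least 2 was also required, 6238 of 12020 tested in the M4 counts, where the cause was not tested, and 9218 to 10994 with a library left out, where fewer libraries were compared. The 6 other alternatives stayed within 1.5 times. The coefficient of variation of 0.396 became 0.581 with no filter, 0.233 with a mean count of at least 50, 0.226 from the median DESeq2 dispersion, 0.208 in the M4 counts, and 0.329 to 0.435 with a library left out; the cause was not tested. The number of detected genes (9 alternatives), of lists at or above percentile 95 (7) and of pairs apart (8) stayed within 1.5 times of the main value. The number of lists at or below percentile 5 went from 0 to 10 against random lists of genes with a mean TPM of at least 1, and ran from 0 to 1 with a library left out. The effector cytokine, NK, gamma delta T, myeloid, dendritic, erythroid and stromal lists have medians under 1 TPM. Their place below genes with a mean TPM of at least 1 was therefore largely set in advance. Against those genes, which leave out the silent ones, the proliferation, B cell and plasma cell lists turned from above to below the middle, at percentiles 4.2, 3.63 and 0.01, and so did the CD8 T cell list, at 19.5. Of 160 values of single pairs, 7 were reversed. Of pairs called apart, Prdm1 minus Bach2 became 0.22 in CPM without length correction, and in the M4 counts per kilobase Ikzf2 minus Ikzf4 became -0.0044 and Slc2a3 minus Slc2a1 -0.21. Of pairs not called apart, Il2ra minus Il7r became -0.80, Cxcr3 minus Ccr7 0.17 and Tnfrsf18 minus Tnfrsf4 0.16 in those counts, and Cxcr3 minus Ccr7 ran from -0.26 to 0.16 with a library left out. A further 3 values, of Id2 and Id3 and of Il2ra and Il7r, changed sign without being apart. Tcf7 minus Lef1 was 0.11 and no longer apart in the M4 counts, where Gata3 minus Tbx21 was 1.18 and Entpd1 minus Nt5e -0.57, and 2 values with library 1 left out became apart in the same direction; the cause was not tested. Of 928 values of named genes, 865 moved by at most 1 SD and 63 by more. Leaving out 1 of 3 libraries cannot move a mean by 1 SD of those libraries. For that alternative the outcome was set in advance, and only the posterior mean TPM could move a level that far. The 4 list ratios between libraries that were recomputed kept their direction and lay outside the central 95% of random lists under each of 4 alternatives. The DESeq2 size factors and total-count scaling shift the log ratios of all genes by the same amount. Those alternatives could therefore not change a place among random lists, and the gap between the lists was 0.95 with either and without the salivary genes. Removing the salivary genes moved the activated median only from 0.569 to 0.568, so it hardly tested that place either. In the M4 counts the 4 ratios moved by over 1.5 times, from 0.57 to 0.31 and from -0.38 to -0.16 (activated and resting genes, library 1 over 2), from 0.95 to 0.46 (their gap) and from 0.76 to 0.40 (interferon genes, library 1 over 3). The -0.16 lay inside the random range of -0.17 to 0.21; the cause was not tested. Genes with mean counts from 10 to 100 held 4322 of the 4925 ratios of at least 2. All of these passed the test against Poisson counting noise of reads, and their cause was not tested.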

Other observations

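The tests on the M21 quantification, on depth and on the M4 counts were chosen only after the result was seen, and so were the random lists and the second median for salivary genes and the versions of the gene filter for the M4 counts.

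Use of T cell receptor gene segments was not tested between libraries. Of the expected counts on beta chain variable segments, family Trbv13 took 22.4 ± 2.47% (SD, n = 3), Trbv3 14.6 ± 1.18% and Trbv16 8.01 ± 1.30%. On the alpha chain, Trav7 took 15.1 ± 1.41% and Trav14 14.9 ± 2.28%. Chosen after their values were seen, Trav3 took 6.81 ± 2.22% of alpha segments and Trbv31 4.56 ± 1.48% of beta segments. Members of a family are closely related, so counts of single segments were not compared.

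Some genes, chosen after their values were seen, were absent from 1 library. In library 2, 10 protein-coding genes with a small posterior standard deviation of the count had 0 counts against at least 50 in both others, among them Kit with 107, 0 and 133 counts and the chemokine Cxcl2. Each of the 10 also had at most 3 M4 counts there. No such gene was found in libraries 1 or 3. Library 2 also had fewer genes with any count, 26665 against 33074 in library 1 and 32146 in library 3. Under the same filter, 8889 protein-coding genes had at least 50 counts in all 3 libraries. Svs4 and Svs5, seminal vesicle proteins, had 98 and 55 counts in library 1 and 0 in the others.

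For the first pattern, the secretory transcripts of library 3, quantification against annotation M21 is argued against as the source, because the M4 counts of 14 of these genes were also higher in library 3, by a median ratio of 325, and RNA of exocrine pancreas because the median count of 10 pancreatic genes in library 3 was 0.00774% of the median of the secretory genes. RNA of salivary gland cells is a candidate explanation: of 15 other salivary genes, the 9 with at least 10 counts had a median ratio of 6.18 for library 3 over the higher of the others, and 8 of the 9 were higher in library 3. Of the 9, 5 reached 10 counts in library 3 alone, which can raise that median, and the median of the 4 that reached it in library 1 or 2 was 1.78. Yet of 10000 random lists matched on mean expression to 13 of the 15 (all but Smr2, which had no count, and Muc19, which is not annotated as protein-coding) and held to the same minimum, 0.140% had a median above 2, and the highest was 3.37. Smr2 and Klk1, abundant in some salivary glands, had 0 and 1 counts in library 3, so the hypothesis does not cover every gland, and how such RNA could have entered 1 library, or whether the unstated gate would remove such cells, was not tested.

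The second pattern is the gap between activated and resting genes, 0.95 on the log2 scale for library 1 over library 2, against at most 0.29 in 10000 matched random list pairs. It was 0.11 for library 1 over library 3, inside the random range, and -0.74 for library 2 over library 3, so library 2 stands apart; in the M4 counts the first gap was 0.46, against at most 0.30. GC content and transcript length are argued against, because the gap was 1.04 after a fit on both, above a random maximum of 0.44. Library 2 had fewer genes with any count, 26665 against 33074 in library 1 and 32146 in library 3. Loss of weakly expressed genes there is argued against as the source of the gap. Among members with a mean count of at least 1000, which were 19 of the 24 activated and 15 of the 16 resting genes, the gap was 0.87, above a random maximum of 0.27. For a difference in read depth, the gap was 0.93 after thinning to 1 total, above a random maximum of 0.29, but this test cannot tell. Thinning moved the members by a median of 0.0054, under the SD of 0.0686 of random list pairs, so it could hardly change the gap. Thinning covers the number of reads only, not other differences between the libraries. No biological explanation was tested because the design names no group that differs between libraries.

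The third pattern is in the M4 counts, whose median ratio to the M21 expected counts in library 1 was 0.519 for genes with 100 to 1000 counts and 0.0101 for those from 100000 upward. Keeping 1 read per start position is a candidate explanation: among the 100 genes with the highest expected counts, the M4 count followed exonic length across genes with a Spearman rho of 0.56 and reached at most 1.92 per exonic base, but 10 of the 100 had under 0.1 per exonic base and 4 of these (mt-Co2, mt-Co3, mt-Atp6 and Hnrnpu, chosen after their values were seen) had no M4 count, which it does not account for. Leaving out reads that map to several places stays open: for 28 genes at least 50 times higher in 1 library, the ratio of M4 to M21 counts where abundant was a median of 0.238 times that where rare, with a 95% bootstrap interval of 0.141 to 0.457. That lies below the 0.5 it would need as the whole cause but spans the bound of 0.25 set for excluding it, and 22 of the 28 had under 10 counts where rare. Of the 28, 24 had a lower ratio where abundant, and the 6 with at least 10 counts where rare had a lower median, 0.105. Across 12 versions of the filter and of the handling of the 7 genes with no M4 count elsewhere, the median over genes ran from 0.0983 to 0.238. The main value is the one that keeps to the criterion as written, with every such gene kept.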
